A study of Mus musculus with 21 samples.

How the data were processed

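The data are 21 Agilent 2-colour microarrays of mammary tumours from mice carrying MMTV-ATX, MMTV-LPA1, MMTV-LPA2 or MMTV-LPA3, with 5 mice per transgene. Per the labels, RNA was extracted with a Qiagen RNeasy kit, the tumour was labelled with Cy5 and a whole-mouse total RNA reference with Cy3 on every array, without a dye swap. The values used are the authors' processed log2 ratios in the deposited value table, 1 per feature and array. The sources used here do not give the scanner processing, the background correction or the normalization. The log base is not given in the sources used here either and was taken as 2 from the range of the values (−11.44 to 9.86). The direction, tumour over reference, follows from the dyes in the labels, and liver and brain genes lay below 0 in all tumours. Every array had a median of 0, so the arrays were centred before deposit. Pairs of arrays correlated at 0.259 to 0.794 over features.

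The table holds 45220 features. The platform annotation gave 1 gene symbol for 33653 of them, several for 56 and none for 11511. Features with several symbols were left out of gene values, and features without one stay unnamed. For 33517 features the symbol was matched to the reference table by gene number. Probes of the same gene were averaged, which gave 19087 genes, 8343 of them from more than 1 feature. Of the values, 628 were missing, on 19 of 21 arrays. A gene was tested when at least 4 tumours of every genotype had a value, which left 19069. The table holds no signal over background, so no filter on dim probes was possible, and a log2 ratio of exactly 0 on an array (3173 to 3916 features on slides 5 and 6, 2180 to 3529 on the others) was kept as deposited.

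Groups were taken from the labels of the tumour channel. The slide and the position on it were read from the array titles. Slides 1 to 4 form the first slide set and slides 5 and 6 the second. The first array of LPA1 mouse 4 was on slide 7 and its repeat on slide 4. Both were averaged before the fit, and the repeat stood for this tumour wherever the slide was a term.

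The genes were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with all 20 tumours in 1 fit, 16 residual degrees of freedom and no covariate. The comparisons were the moderated F test over the 4 genotypes, ATX against the mean of the receptor genotypes, the 3 receptor pairs, and ATX against each receptor. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes. All adjusted p-values of genes come from limma and rest on the spread within genotypes. In the fit without the slide that spread holds differences between mice and between slides. Those of lists come from its function camera, which compares the statistics of a list's genes with those of all other genes under an assumed correlation. The p-values of lists do not measure that spread by themselves.

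The 25 gene lists were LPA axis, luminal epithelium, hormone sensing, basal keratinocyte and myoepithelium, squamous differentiation, epithelial junction, mesenchymal transition, milk, cell division, Wnt targets, hypoxia and glycolysis, immediate early and stress, inflammatory and angiogenic mediators, interferon response, class II antigen presentation, macrophage, neutrophil, T and NK cell, B and plasma cell, fibroblast and collagen, endothelium, adipocyte, skeletal muscle, liver and brain. They held 396 entries, of which 370 were measured. Each list was tested with camera (preset correlation 0.01), adjusted over 25 lists and 4 comparisons in 1 family of 100 tests. The count of members passing over all genes and adjusted over the list alone was also taken. A camera p with an estimated correlation and limma's fry were the alternatives. The score of a list in a tumour is the mean over its members of the log2 ratio minus the mean of the gene over the tumours.

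Similarity of tumours, relations between lists and single scores were tested by permutation (1e+05 resamples, or exact over all orderings or splits) in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Figures were drawn with matplotlib 3.10.9. Tests of relations and of scores are two-sided and the test of similarity one-sided.

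Groups, tests, lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 genes of smallest p of the F test. For each directional comparison with 10 or more calls it took up to 12 called genes of largest size in each direction. With fewer, it took every called gene and, as values, the 5 of smallest p in each direction. It added up to 4 members of largest size per list, Enpp2 and Lpar1 to Lpar6, the 12 genes of highest and of lowest mean against the reference, and the 12 of largest SD. Enpp2 and Lpar5 were not analysed here.

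The fit was tested on simulated tumours with the spread of the real genes, drawn independently per gene, and 200 changed genes among 19069. For ATX against the receptors 157 were recovered (34% of those changed by 1 on the log2 scale, 88% at 2, 92% at 3 and 100% at 4), with 6 false among 163 calls. For LPA3 against LPA1 135 were recovered (22%, 60%, 88% and 100% at the same sizes), with 5 false among 140. For LPA2 against LPA1, simulated without a change, 0 genes were called. The F test recovered 137 of 200 with 8 false calls. In a simulation of ATX against the receptors camera called the 1 shifted list and 0 of the others. That simulation held no correlation between genes, so it does not show how often camera calls lists of correlated genes.

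The alternatives fixed beforehand were centring and quantile normalization of the arrays, every probe alone or the probe of largest SD per gene, filters on missing values, a robust variance model with trend, array weights, the slide as a random or fixed block, the slide set as a covariate, either array of LPA1 mouse 4 alone, the mouse number as a block, an adjusted p under 0.1, only the groups compared, the 2 other list tests, a size limit of 2 against the reference, and leaving out each tumour in turn. After seeing the data 5 were added: arrays scaled to the same spread, the run of slides as a block, only slides 1 to 4, only slides 5 and 6, and the 2 pairs of near-identical tumours counted as 1 sample each. Centring left every value as it was, and the largest shift of the median of all genes under quantile normalization or equal spread was 0.00964.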

Results

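Gene expression was measured in mammary tumours of mice that carried 1 of 4 transgenes under the MMTV promoter, which is active in the mammary epithelium. The transgenes were ATX (autotaxin, the secreted enzyme that makes lysophosphatidic acid, LPA) or 1 of the LPA receptors LPA1, LPA2 and LPA3. Each transgene was represented by 5 mice, 1 tumour each, which gave 20 tumours on 21 Agilent 2-colour arrays, since the tumour of LPA1 mouse 4 was hybridised on 2 arrays. The mice are separate animals per the labels. The spread within a group holds that between mice and, since each genotype lay on several slides, that between slides. Every tumour was labelled with Cy5 and compared on the same array with whole-mouse RNA labelled with Cy3. No array held normal mammary gland, and the dyes were not swapped. All values are log2 ratios of tumour to reference unless stated otherwise, and the log base, taken as 2, was not stated in the sources used here. The number of arrays limits the precision.

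The arrays fell into 2 kinds by slide. On slides 5 and 6, which held 7 arrays (LPA1 1, 2 and 5, LPA2 1, 2 and 5, and LPA3 4), the SD of the log2 ratios within an array was 0.825 to 0.903. On the 14 other arrays it was 1.195 to 1.432. Liver genes, which a whole mouse holds and a mammary tumour lacks, had list medians of −1.115 to −0.755 on slides 5 and 6 and −4.515 to −2.644 elsewhere. The medians of adipocyte genes averaged 0.178 ± 0.727 (SD, n = 7 arrays) on slides 5 and 6 and −2.68 ± 1.37 (SD, n = 14) elsewhere, and those of skeletal muscle genes −0.384 ± 0.522 and −3.45 ± 0.865. Between the slide sets 2361 genes differed in limma, 1829 of them higher on slides 5 and 6. The genotypes were spread unevenly over the slides, with 0 of 5 ATX, 3 of 5 LPA1, 3 of 5 LPA2 and 1 of 5 LPA3 tumours on slides 5 and 6. Values with the slide set as a covariate, with the slide as a block, on slides 1 to 4 alone and, for the receptors, on slides 5 and 6 alone are therefore given with the results, in particular where a call ends in one of these settings. The last setting holds 1 LPA3 tumour, which was assumed to vary like the other groups. The settings restricted to some slides were chosen after seeing the data.

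**Figure D1:**
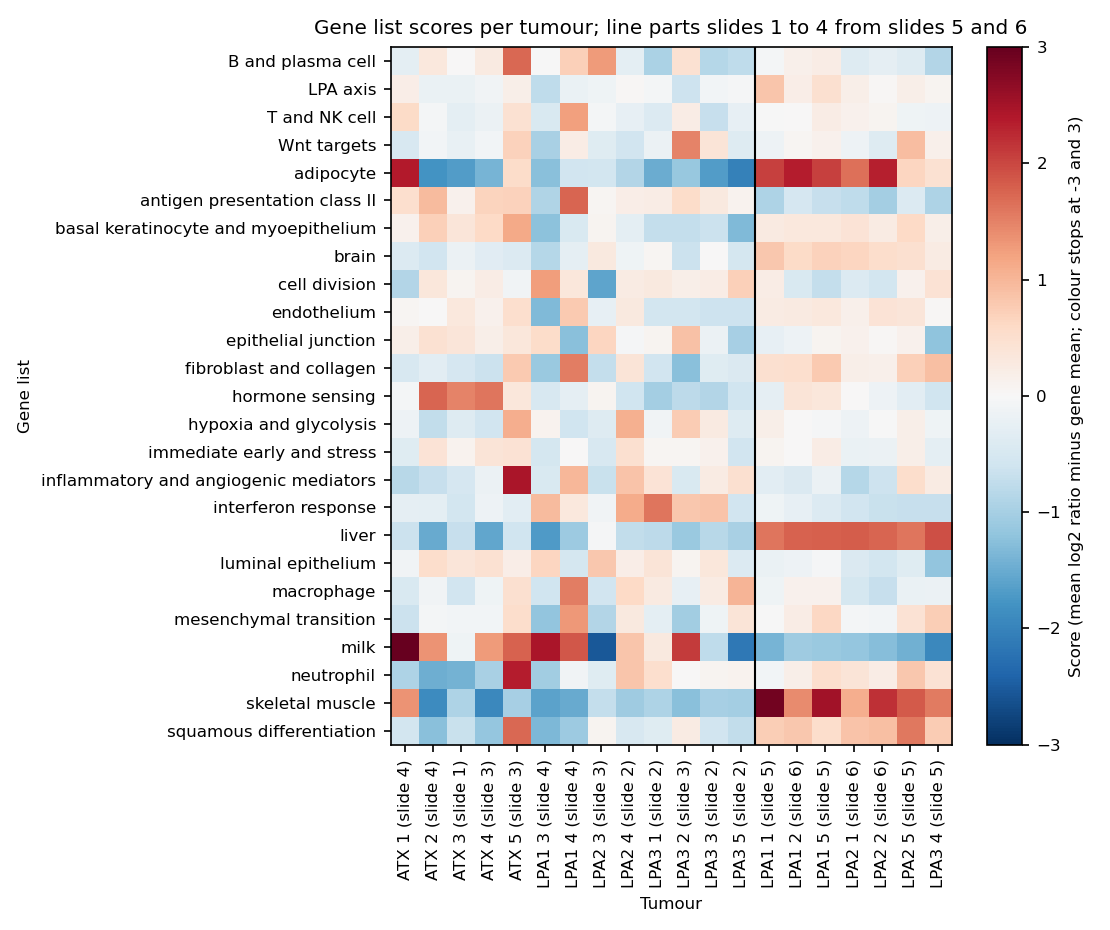
Score of each of the 25 gene lists (from top to bottom) in each of the 20 tumours (columns, with the slide of each), as the mean log2 ratio of the members minus each gene's mean over the tumours. Colour runs from −3 (blue) to 3 (red), and the vertical line parts tumours on slides 1 to 4 from the 7 on slides 5 and 6, where liver and skeletal muscle genes had higher scores and milk genes lower ones.

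Against the whole-mouse reference, the tumours carried high levels of milk protein and luminal epithelial transcripts. Csn2 (beta-casein) had a mean log2 ratio of 5.34 ± 3.27 (SD, n = 20), Csn1s2a 4.66 ± 2.84, Csn3 3.55 ± 2.1 and Csn1s1 2.99 ± 1.47, all caseins. Elf5, a transcription factor of the luminal and alveolar epithelium, had 3.21 ± 1.32, the stromelysin Mmp3 4.23 ± 1.7 and the chemokine Ccl8 3.45 ± 1.41. Gja10 (3.45 ± 2.65), C130026I21Rik (3.18 ± 1.47), Itprid1 (3.12 ± 1.36), Plet1 (2.90 ± 1.47) and Tpra1 (2.81 ± 1.34) completed the 12 genes of highest mean. The lowest means belonged to Atp1b4 (−4.88 ± 2.87), the neural transcription factor Zic1 (−4.79 ± 1.56), Ambp (−4.73 ± 2.09), alpha-fetoprotein Afp (−4.72 ± 2.76), Kprp (−4.68 ± 1.34), the liver fatty acid binding protein Fabp1 (−4.50 ± 2.8) and Cyp4a14 (−4.50 ± 1.72). They were followed by Rgn (−4.37 ± 1.47), Itm2a (−4.32 ± 2.3), Cfi (−4.30 ± 2.01), Aadac (−4.30 ± 1.36) and S100g (−4.28 ± 1.43). Of the 18922 genes measured in all 20 tumours, 268 were above the reference in all of them with a mean of at least 1, and 1017 were below it in all with a mean of −1 or less. No test was applied to these ratios, and a dye bias of a probe stays in them. Their order pools the slide sets and differs between them. Csn2 had means of 7.09 on slides 1 to 4 and 2.09 on slides 5 and 6, and Gja10 2.82 and 4.62. Atp1b4 had −6.88 and −1.16 in the same order, and Zic1 −5.81 and −2.89.

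By gene list, the median of the milk genes lay above the reference in 20 of 20 tumours (mean of the medians 2.61), as did those of class II antigen presentation (1.43, with H2-DMb1 at 2.72 ± 0.722, n = 20) and macrophage genes (0.985). The luminal list was above it in 19 tumours (1.20) and the epithelial junction list in 17 (0.857). Liver (−2.84) and brain (−1.38) genes were below it in all 20 tumours, fibroblast and collagen genes in 19 (−1.08, with Col1a1 at −2.26 ± 1.48), and skeletal muscle (−2.35), mesenchymal transition (−0.725) and squamous differentiation genes (−1.38) in 18. Basal keratinocyte and myoepithelial genes were below it in 17 (−0.536). On slides 5 and 6 the means of the milk and liver medians were 1.35 ± 0.411 and −1.01 ± 0.135 (SD, n = 7), against 3.29 ± 1.76 and −3.83 ± 0.508 (n = 13) on slides 1 to 4.

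Across the 4 genotypes, 6 genes differed in limma's moderated F test. Esr1, the oestrogen receptor, had 2.87 ± 0.867 in ATX, 1.77 ± 0.276 in LPA1, 0.63 ± 0.859 in LPA2 and −0.13 ± 0.486 in LPA3 tumours (SD, n = 5 each; adjusted p = 0.02). Slc16a9, a monocarboxylate transporter family member, had means of 1.80 ± 0.27, 1.10 ± 0.498, 0.21 ± 0.72 and −0.96 ± 0.645 in the same order (adjusted p = 0.014). Tnfsf11, the RANK ligand that relays progesterone signals in the mammary gland, had 3.89 ± 1.29 in ATX and between −0.14 and 0.54 in the receptor genotypes (adjusted p = 0.0386). Wfdc12, of the whey acidic protein family, ran from 3.77 ± 0.84 in ATX to −1.14 ± 1.47 in LPA3 (adjusted p = 0.0407). Nabp1, a single-stranded DNA binding protein, had 2.02 ± 0.161 in ATX and 0.68 ± 0.193 to 1.12 ± 0.326 in the receptor genotypes (adjusted p = 0.0386). The uncharacterised 4933406I18Rik had 2.65 ± 1.04 in LPA3 and −0.05 ± 0.089, 0.12 ± 0.156 and 0.43 ± 0.584 in ATX, LPA1 and LPA2 (adjusted p = 0.014).

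The next genes by p did not pass, with limma adjusted p-values of 0.0575 for Ggt5, 0.0582 for Tph1, 0.0836 for Ddah1, 0.0899 for Cck, 0.0899 for Rspo1 and 0.0927 for Lgi2. With the slide set as a covariate 14 genes differed, and the adjusted p of Nabp1 was then 0.259. With the slide as a fixed block, or on slides 1 to 4 alone, the limma F test called 0 genes, with 1050 and 1785 at an unadjusted p under 0.05. On slides 5 and 6 alone this test cannot be compared, since they hold no ATX tumour and 1 LPA3 tumour. Leaving out ATX 2 or ATX 4 also gave 0, and leaving out ATX 1 gave 37. The 11 probes of Esr1 did not all follow each other, with a lowest correlation of −0.0529 between probes.

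The comparison of ATX with the mean of the 3 receptor genotypes asks whether tumours of mice with the enzyme transgene differ from those with an LPA receptor transgene. Tnfsf11 and Esr1, active in hormone-responsive mammary cells, rose in ATX tumours. Tnfsf11 was higher by 3.74 (SE 0.521, adjusted p = 0.0122 in limma) and Esr1 by 2.12 (SE 0.333, adjusted p = 0.0159). Sostdc1, an inhibitor of BMP and Wnt signals, was higher by 3.68 (SE 0.703, adjusted p = 0.0465). The chemokine Ccl20 rose by 3.93 (SE 0.742), from means of −0.70 to 1.89 in the receptor genotypes to 4.31 ± 2.57 in ATX (SD, n = 5). Tph1, which makes serotonin, rose by 2.39 (SE 0.362), from means of −0.11 to 0.53 to 2.68 ± 1.17.

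In all, 19 genes differed, 16 higher and 3 lower. With array weights the count was far larger and most of the genes called were lower in ATX, as given below. The other genes among the 12 largest increases were Slitrk6 (3.99, SE 0.759), Wfdc12 (3.20, SE 0.563), Slc35f3 (2.63, SE 0.463), Pnmt (2.61, SE 0.432), Nmb (2.44, SE 0.433), Apol10b (2.07, SE 0.392) and Pcdhb11 (1.75, SE 0.33). Pnmt encodes the enzyme that makes adrenaline and Nmb the peptide neuromedin B. The limma SEs pool the spread over the genotypes, and some of these genes spread more in ATX. The SDs in ATX were 1.73 for Slc35f3, 1.45 for Pnmt and 1.69 for Nmb, against at most 0.804 in the receptor genotypes. For such genes the SEs and p-values may be too small. Wfdc12, with 0.84 in ATX and 0.342 to 1.59 in the receptor genotypes, was not such a gene. The 3 lower genes were Ddah1, which breaks down an inhibitor of nitric oxide synthesis (fell by 1.68, SE 0.259, adjusted p = 0.0155), the secreted C1qtnf3 (fell by 2.24, SE 0.428, adjusted p = 0.0465) and the enamel gene Ambn (fell by 2.31, SE 0.42, adjusted p = 0.0417). The count was 27 with the slide set. All 19 kept their direction there (10 still called), with the slide as a block (0 called, 1489 genes at an unadjusted p under 0.05) and on slides 1 to 4 (0 called, 1247 genes). Of the 19, 18 had an unadjusted p under 0.05 with the slide as a block, and Ambn, at −0.70 there, was the exception. Without ATX 2 the count was 0 and without ATX 4 it was 1. It was 116 without ATX 1, 68 without ATX 5 and 42 without LPA1 3.

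**Figure D2:**
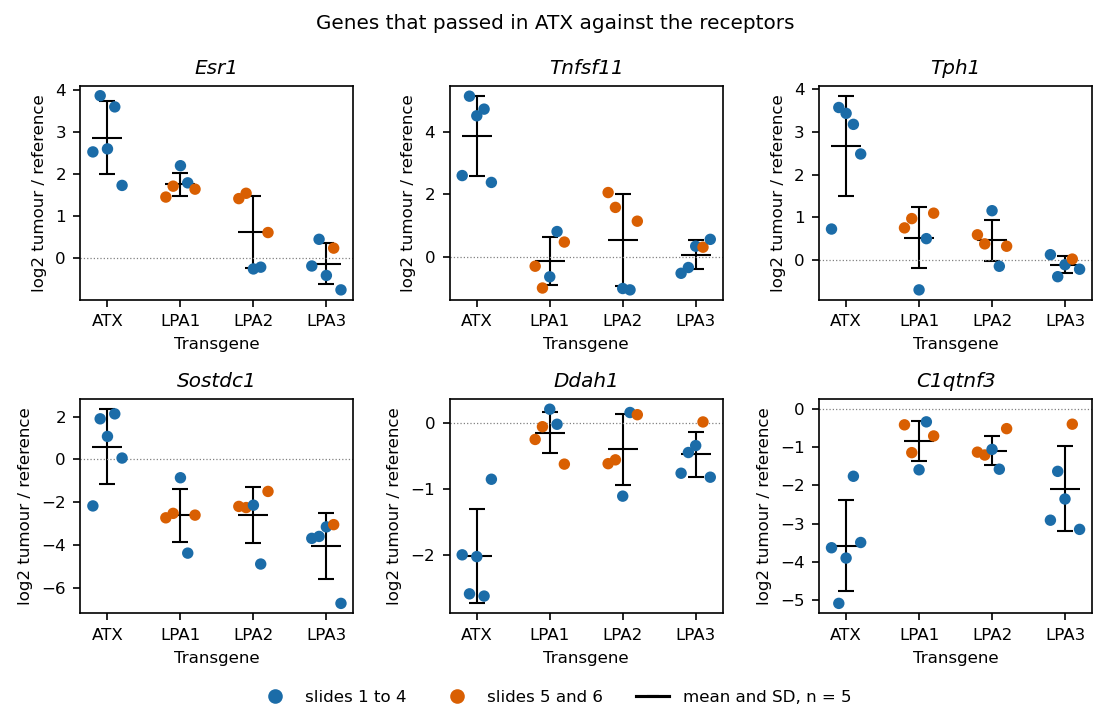
Log2 ratios of tumour to reference (vertical axes) of 6 genes that passed in ATX against the receptors, by transgene (horizontal axes). Points are tumours, blue on slides 1 to 4 and orange on slides 5 and 6, and black lines give the mean and SD (n = 5). Esr1, Tnfsf11, Tph1 and Sostdc1 were higher and Ddah1 and C1qtnf3 lower in ATX, with means of 2.87, 3.89, 2.68, 0.60, −2.02 and −3.58.

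Of the 10 measured genes of the hormone sensing list, 9 were higher in ATX, with a median difference of 1.03 (camera, adjusted p = 6.75e-08; adjusted p = 0.199 with an estimated correlation). Of these, 5 passed when adjusted over the list alone and 2, Tnfsf11 and Esr1, over all genes. The others among the largest were Cited1, a coregulator of the oestrogen receptor (2.31, SE 0.476, adjusted p = 0.00036 over the list alone), and Wnt4, a progesterone target (1.80, SE 0.487, adjusted p = 0.00376 over the list alone). The median difference was 1.41 with the slide set, 1.24 with the slide as a block and 1.44 on slides 1 to 4, with an adjusted p of 0.0828, 0.375 and 0.516 with an estimated correlation. By score, ATX tumours had 1.03 ± 0.834 (SD, n = 5), with 1.75, 1.499 and 1.62 in ATX 2, 3 and 4, 0.33 in ATX 5 and −0.07 in ATX 1. LPA1, LPA2 and LPA3 tumours had −0.06 ± 0.393, −0.20 ± 0.275 and −0.77 ± 0.184.

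All 14 milk genes were higher in ATX, with a median difference of 1.89 (camera, adjusted p = 1.46e-08; adjusted p = 0.746 with an estimated correlation). Over the list alone 8 passed, among them Csn2 (4.03, SE 1.33), Csn1s2a (3.16, SE 1.2), Glycam1 (2.64, SE 0.865) and Csn3 (2.55, SE 0.836). The median was 1.05 with the slide set, 0.86 with the slide as a block and 1.05 on slides 1 to 4. Of the 15 basal keratinocyte and myoepithelial genes 14 were higher (median 0.50, adjusted p = 6.78e-05; adjusted p = 0.746 with an estimated correlation). Of these, 3 passed over the list alone: Cnn1, a smooth muscle protein of myoepithelial cells (2.48, SE 0.607), the hemidesmosome collagen Col17a1 (2.26, SE 0.546) and Moxd1 (1.77, SE 0.593). Their median was 0.82, 1.20 and 0.86 in the same 3 slide settings, where the list was called with an estimated correlation too (adjusted p = 0.00845, 0.02 and 0.0289). With the slide set 7 genes passed over the list alone. The last 2 of these 3 p-values were computed after the others were seen. Endothelial genes rose by less (median 0.21, 13 of 15 higher, adjusted p = 0.0122; adjusted p = 0.779 with an estimated correlation). Among them Vwf passed over the list alone (1.02, SE 0.297), and the slide settings gave medians of 0.50, 0.59 and 0.49. The endothelial call ended without ATX 5 (0.12, adjusted p = 0.0855) or without LPA1 3 (0.12, adjusted p = 0.0792), and with arrays weighted by quality the median was 0.05.

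For 7 other lists the call ended with the slide set as a covariate. Class II antigen presentation genes were higher by a median of 0.88 (10 of 10, adjusted p = 0.000157), with H2-Aa at 1.40 (SE 0.534) and H2-Oa at 1.40 (SE 0.379, adjusted p = 0.015 over the list alone). Their adjusted p was 0.746 with an estimated correlation, and with the slide set the median was 0.25 (adjusted p = 0.169). B and plasma cell genes were higher by 0.48 (10 of 11, adjusted p = 0.00469; 0.27 and 0.181 with the slide set; adjusted p = 0.746 with an estimated correlation), with Jchain at 1.85 (SE 0.716). Epithelial junction genes were higher by 0.47 (14 of 16, adjusted p = 0.00696; 0.33 and 0.0802), and luminal genes by 0.21 (14 of 17, adjusted p = 0.037; −0.06 and 0.908), with Gata3 at 1.84 (SE 0.524). Both had an adjusted p of 0.746 with an estimated correlation. On slides 1 to 4 junction genes were still called (0.39, adjusted p = 0.0268; adjusted p = 0.898 with an estimated correlation). Liver genes were lower by a median of −1.38 (13 of 13, adjusted p = 5.41e-06; −0.02 and 0.524 with the slide set; adjusted p = 0.746 with an estimated correlation), with Apoa2 at −1.95 (SE 0.746). Skeletal muscle genes had −1.25 (15 of 15 lower, adjusted p = 0.00164; 0.24 and 0.0876) and brain genes −0.44 (8 of 12 lower, adjusted p = 0.0276; −0.30 and 0.524), with Nefl at −1.79 (SE 0.489). For these 2 lists an estimated correlation gave adjusted p-values of 0.806 and 0.746. Muscle genes were called upward, the other way, with the slide as a block (0.46, adjusted p = 0.0398; adjusted p = 0.905 with an estimated correlation). Of these calls, 3 ended when 1 tumour was left out. Without ATX 5 B and plasma cell genes had 0.31 (adjusted p = 0.207), and brain genes had −0.39 (adjusted p = 0.0549), as they had −0.37 without ATX 1 (adjusted p = 0.0866). The luminal call ended without ATX 2, ATX 3, ATX 4, LPA1 4, LPA2 1, LPA2 2, LPA3 4 or LPA3 5 (medians of 0.16, 0.19, 0.20, 0.13, 0.18, 0.16, 0.14 and 0.21; adjusted p = 0.0515 to 0.0957). Luminal medians without ATX 1, LPA2 3 and LPA3 2 were 0.46, 0.34 and 0.14.

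The 14 remaining lists were not called in this comparison. Interferon response genes had a median of −0.53 (adjusted p = 0.0623), which the slide set made −0.86 (adjusted p = 5.51e-09; adjusted p = 0.528 with an estimated correlation). Adipocyte genes had −0.52 (adjusted p = 0.289; 0.67 and 0.0117 with the slide set) and macrophage genes −0.21 (adjusted p = 0.393; −0.53 and 0.0109). For these 2 lists an estimated correlation gave adjusted p-values of 0.872 and 0.863 with the slide set. The slide as a block gave medians of −0.68, 1.13 and 0.01 for the 3 lists (adjusted p = 0.00176, 0.00331 and 0.909), and slides 1 to 4 gave −0.84, 0.68 and −0.54 (adjusted p = 6.63e-08, 0.0068 and 0.0266). Immediate early and stress genes had 0.25 (adjusted p = 0.0517), squamous differentiation −0.42 (0.0885), fibroblast and collagen −0.36 (0.146), neutrophil −0.38 (0.203) and hypoxia and glycolysis −0.25 (0.246). Inflammatory and angiogenic mediators had 0.18 (adjusted p = 0.342), T and NK cell 0.12 (0.394), mesenchymal transition −0.14 (0.763) and cell division genes −0.04 (0.902). Wnt targets had a median of 0.03 and a mean of −0.05 (adjusted p = 0.972), and the LPA axis a median of −0.18 with an upward direction in camera (adjusted p = 0.454). Called with the slide as a block were the LPA axis (0.46, adjusted p = 0.00146), immediate early and stress (0.37, adjusted p = 0.00764) and mesenchymal transition genes (0.37, adjusted p = 0.0358). An estimated correlation gave them adjusted p-values of 0.101, 0.775 and 0.905 there. The LPA axis had 0.22 with the slide set (adjusted p = 0.0559) and 0.27 on slides 1 to 4 (adjusted p = 0.0793). Cell division genes were called on slides 1 to 4 (−0.27, adjusted p = 0.0485), where with an estimated correlation the adjusted p was 0.749 for interferon response genes and 0.898 for adipocyte, macrophage and cell division genes. In the block fit it was 0.867 for interferon response and 0.905 for adipocyte genes.

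The transgenes act on the LPA axis itself. The array probes of Lpar1, Lpar2 and Lpar3 did not tell their own transgenic genotypes apart: Lpar1 had −1.73 ± 0.528 in ATX, −0.58 ± 1.3 in LPA1, −0.84 ± 0.66 in LPA2 and −1.37 ± 1.27 in LPA3 tumours (SD, n = 5 each). Lpar2 had 1.16 ± 0.557, 0.64 ± 0.76, 0.58 ± 0.479 and 1.25 ± 1.03, and Lpar3 −0.72 ± 0.13, −0.76 ± 0.865, −0.62 ± 0.291 and 0.08 ± 1.66 in the same order. Lpar1 had −2.89 in LPA1 3 and −0.196 to 0.302 in the other LPA1 tumours. Lpar3 reached 1.01 and 2.04 in LPA3 1 and LPA3 3. For Lpar1 the limma adjusted p was 0.699 in LPA3 against LPA1 (−0.791, SE 0.595). Limma adjusted p-values were 0.999 for Lpar1 and Lpar2 in LPA2 against LPA1, and for Lpar3 0.661 in LPA3 against LPA1 (0.84, SE 0.562) and 0.675 in LPA3 against LPA2 (0.70, SE 0.562). The labels do not say which species or part of each receptor the transgenes held, so these probes check nothing about them. In ATX against the receptors the adjusted p was 0.516 for Lpar1, 0.752 for Lpar2, 0.843 for Lpar3, 0.709 for Lpar4 and 0.218 for Lpar6 (0.44, SE 0.138). Of the 13 measured genes of this list, 2 were higher in ATX adjusted over the list alone, Lpar6 and the LPA phosphatase Plpp3 (1.14, SE 0.282, adjusted p = 0.00897), and 0 over all genes in limma. Plpp3 was chosen after its values were seen. Enpp2, which encodes autotaxin, and Lpar5 were not analysed here.

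Set against each receptor genotype in turn, ATX differed from LPA1 in 0 genes in limma (1715 at an unadjusted p under 0.05), from LPA2 in 1 and from LPA3 in 19. The gene called against LPA2 was Nabp1 (1.34, SE 0.191, adjusted p = 0.0207). Against LPA3, 17 genes were higher and 2 lower in ATX. The largest increases were in Rspo1, a Wnt pathway agonist (6.53, SE 1.06, adjusted p = 0.0193), Ccl20 (5.01, SE 0.909), Wfdc12 (4.92, SE 0.69), Sostdc1 (4.64, SE 0.861) and Cnn1 (4.24, SE 0.743). The 2 lower genes were 4933406I18Rik (−2.70, SE 0.371, adjusted p = 0.00404) and Acox2 (−1.83, SE 0.345, adjusted p = 0.04). Genes of these 3 comparisons were named after their values were seen. With the slide set the limma counts were 0, 0 and 80 (1229, 1383 and 2439 at an unadjusted p under 0.05), with the slide as a block 0, 0 and 0 (1120, 1365 and 1385), and on slides 1 to 4 they were 0, 1 and 5 (1179, 1502 and 1893). The gene called against LPA2 on slides 1 to 4 was another than Nabp1.

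LPA2 and LPA1 tumours differed in 0 genes in limma, with 697 at an unadjusted p under 0.05. By list, macrophage genes were lower in LPA2 by a median of −0.50 (13 of 13, camera adjusted p = 0.000566; adjusted p = 0.746 with an estimated correlation), with the F4/80 gene Adgre1 at −0.95 (SE 0.327) and lysozyme Lyz2 at −0.63 (SE 0.314). Squamous differentiation genes were higher in LPA2 by 0.69 (19 of 20, adjusted p = 0.00259; adjusted p = 0.746 with an estimated correlation), with the transglutaminase Tgm3 at 1.74 (SE 0.883) and Sbsn at 1.11 (SE 0.618). Both lists held their direction within each slide set, with −0.36 and −0.57 for macrophage and 1.20 and 0.51 for squamous genes on slides 1 to 4 and on slides 5 and 6. With the slide as a block they had −0.74 and 0.30. The call of macrophage genes ended on slides 1 to 4 (adjusted p = 0.0691). It also ended without LPA1 4 (−0.20, adjusted p = 0.286), whose macrophage score was 1.544, while the other LPA1 tumours had −0.606 to 0.134. Without LPA1 3 the macrophage median was −0.77. The squamous call ended without LPA1 3 (0.31, adjusted p = 0.0842), LPA1 4 (0.41, adjusted p = 0.0673) or LPA2 5 (0.36, adjusted p = 0.0985), so it was kept in 17 of 20 fits that left 1 tumour out.

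Cell division genes were lower in LPA2 by a median of −0.54 (24 of 24, adjusted p = 6.75e-08; adjusted p = 0.746 with an estimated correlation), with the mitotic kinases Bub1 at −1.17 (SE 0.628) and Aurkb at −1.05 (SE 0.555). Milk genes were lower by −1.26 (14 of 14, adjusted p = 2.31e-05; adjusted p = 0.746 with an estimated correlation), with Csn2 at −1.84 (SE 1.62) and Muc15 at −1.71 (SE 0.889). These 2 relations did not hold within both slide sets. On slides 1 to 4 (2 tumours each) the medians were −1.33 and −3.10, and on slides 5 and 6 (3 tumours each) 0.04 (adjusted p = 0.374) and −0.12 (adjusted p = 0.329). With the slide as a block they were −0.37 and −0.77. Epithelial junction genes were higher by 0.31 (14 of 16, adjusted p = 0.0122; 0.0744 with the slide as a block and 0.0547 on slides 1 to 4), with the desmosomal Pkp3 at 0.92 (SE 0.334), and had an adjusted p of 0.746 with an estimated correlation. T and NK cell genes were lower by −0.26 (11 of 14, adjusted p = 0.0216; 0.121 with the slide as a block and 0.571 on slides 5 and 6), with Nkg7 at −0.69 (SE 0.404), and likewise had an adjusted p of 0.746 with an estimated correlation. Single tumours moved all 4 lists. Cell division genes had −0.26 without LPA1 3 and −0.32 without LPA2 3, and milk genes −0.71 without LPA1 3 and −0.79 without LPA1 4, all still called. The junction call ended without LPA1 4 (0.07, adjusted p = 0.398) or LPA2 3 (0.24, adjusted p = 0.0708) and the median was 0.58 without LPA1 3. That of T and NK cell genes ended without LPA1 4 (−0.01, adjusted p = 0.712) or LPA2 4 (−0.08, adjusted p = 0.0556) and the median was −0.54 without LPA1 3.

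No single gene passed between LPA2 and LPA1. The smallest p-values upward were those of Prmt8 (1.26, SE 0.308), the carbonic anhydrase Car6 (2.97, SE 0.776), 1700041M19Rik (1.16, SE 0.304), Ppif (0.81, SE 0.214) and Rexo4 (0.77, SE 0.205). Downward they were Gm14461 (−2.62, SE 0.453, adjusted p = 0.27 in limma), Slfn9 (−2.07, SE 0.469), Ggt5 (−1.06, SE 0.25), the immune checkpoint ligand Vtcn1 (−1.83, SE 0.438) and Gm11696 (−0.88, SE 0.22). The adjusted p was 0.999 for all but Gm14461. On slides 1 to 4 alone 6 genes were called, 3 in each direction, and on slides 5 and 6 alone 0 (904 at an unadjusted p under 0.05). The 19 lists not called had adjusted p-values from 0.0623 for basal keratinocyte and myoepithelial genes (median 0.36) to 0.985 for Wnt targets. Of these, 3 were called with the slide set: liver (0.41, adjusted p = 6.56e-05), basal (0.50, adjusted p = 0.0195) and interferon response genes (−0.26, adjusted p = 0.0418; 0.10 and 0.603 on slides 1 to 4). Their adjusted p there was 0.782, 0.782 and 0.892 with an estimated correlation. The slide as a block called liver (0.30, adjusted p = 0.00764), interferon response (−0.47, adjusted p = 0.00764) and B and plasma cell genes (−0.48, adjusted p = 0.0442), with an adjusted p of 0.905, 0.905 and 0.782 with an estimated correlation. Slides 1 to 4 called liver (1.11, adjusted p = 1.18e-05), brain (0.99, adjusted p = 0.0266) and basal genes (0.95, adjusted p = 0.0485), with an adjusted p of 0.749 each with an estimated correlation. For skeletal muscle, immediate early and stress, luminal and Wnt target genes the median, the mean and camera's direction differed in sign.

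Adipocyte genes fell in LPA3 against LPA1 tumours by a median of 2.15 (14 of 14 lower, camera adjusted p = 1.12e-06; adjusted p = 0.746 with an estimated correlation). The fatty acid transporter Cd36 had −3.76 (SE 1.1) and the lipid droplet coat protein Plin4 −3.34 (SE 1.06), both with an adjusted p of 0.0246 over the list alone, where 3 genes passed. Tumours on slides 5 and 6 had more adipocyte signal, as given above, and the median was −1.07 with the slide set, −0.88 with the slide as a block, −0.32 on slides 1 to 4 (adjusted p = 0.474) and −1.61 on slides 5 and 6. B and plasma cell genes fell by 0.911 (10 of 11 lower, adjusted p = 0.00467; adjusted p = 0.746 with an estimated correlation), with the B cell receptor subunit Cd79b at −1.87 (SE 0.58, adjusted p = 0.0494 over the list alone). Their median was −1.02, −1.22, −0.98 and −0.91 in the same 4 slide settings.

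Fibroblast and collagen genes fell by 0.644 (15 of 16 lower, adjusted p = 0.00121; adjusted p = 0.746 with an estimated correlation), with lumican Lum at −2.42 (SE 0.848) and Pdgfra at −1.57 (SE 0.575). Their median was −0.56 with the slide set and −0.64 with the slide as a block, and −0.79 on slides 1 to 4, but 0.36 (adjusted p = 0.0146; adjusted p = 0.651 with an estimated correlation) on slides 5 and 6, where LPA3 had 1 tumour. Endothelial genes fell by 0.497 (15 of 15 lower, adjusted p = 0.00109; adjusted p = 0.746 with an estimated correlation), with VE-cadherin Cdh5 at −1.07 (SE 0.46) and the angiopoietin receptor Tek at −0.83 (SE 0.248). Hormone sensing genes fell by 0.611 (8 of 10 lower, adjusted p = 0.0146; adjusted p = 0.746 with an estimated correlation), with Esr1 at −1.89 (SE 0.408, adjusted p = 0.00177 over the list alone). T and NK cell genes fell by 0.606 (12 of 14 lower, adjusted p = 0.025; 0.29 with the slide as a block; adjusted p = 0.746 with an estimated correlation), with Gzmb at −0.90 (SE 0.629). The endothelial and hormone sensing medians were −0.25 and −0.66 with the slide set and −0.48 and −0.85 with the slide as a block. Both calls ended on slides 1 to 4 (−0.23, adjusted p = 0.236; −0.24, adjusted p = 0.191) and on slides 5 and 6 (−0.27, adjusted p = 0.119; −0.89, adjusted p = 0.113), as did that of T and NK cell genes on slides 5 and 6 (−0.34, adjusted p = 0.15). Without LPA1 4 the calls ended for fibroblast (−0.34, adjusted p = 0.105), endothelial (−0.27, adjusted p = 0.0673) and T and NK cell genes (−0.30, adjusted p = 0.474). The fibroblast call also ended without LPA3 2 (−0.49, adjusted p = 0.0688), and that of T and NK cell genes without LPA3 3 (−0.38, adjusted p = 0.0852) or LPA3 4 (−0.59, adjusted p = 0.0608). Without LPA1 3 the endothelial median was −0.83, and without LPA1 5 the hormone sensing median was −0.40 (adjusted p = 0.0333).

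For 3 lists the call between LPA3 and LPA1 ended or turned with the slide set as a covariate. Skeletal muscle genes had a median of −1.30 (15 of 15 lower, adjusted p = 0.00175; adjusted p = 0.806 with an estimated correlation) and −0.03 with the slide set (adjusted p = 0.923). Liver genes had −0.96 (12 of 13 lower, adjusted p = 0.0402; adjusted p = 0.831 with an estimated correlation). They were called upward, the other way, with the slide set (0.20, adjusted p = 0.0246) and on slides 1 to 4 (0.48, adjusted p = 0.00872), where an estimated correlation gave adjusted p-values of 0.872 and 0.898. Cell division genes had 0.27 (17 of 24 higher, adjusted p = 0.0258; adjusted p = 0.831 with an estimated correlation) and 0.09 with the slide set (adjusted p = 0.439). They were called downward on slides 1 to 4 (−0.43, adjusted p = 0.00443, and 0.898 with an estimated correlation). On slides 5 and 6, where LPA3 had 1 tumour, their median was 0.73. The muscle call ended without LPA1 1 (−0.68, adjusted p = 0.0749) and the median was −0.82 without LPA1 5. The liver call ended without LPA1 1, LPA1 2, LPA1 5, LPA3 1, LPA3 2, LPA3 3 or LPA3 5 (−0.63, −0.59, −0.55, −0.82, −0.74, −0.78 and −0.78; adjusted p = 0.0765 to 0.309), and its adjusted p was 0.000494 without LPA1 3 and 0.000239 without LPA3 4 (−1.53). The cell division call ended without LPA1 2 (0.13), LPA1 5 (0.04), LPA3 4 (0.23) or LPA3 5 (0.15), with adjusted p = 0.0517 to 0.623, and the median was 0.49 without LPA1 3. The 16 other lists had adjusted p-values from 0.0676 (Wnt targets, 12 of 16 higher, median 0.43) to 0.953. Squamous differentiation genes had a median of 0.06 and a mean of −0.06, but 0.57 with the slide set (adjusted p = 0.0016) and 0.77 on slides 1 to 4 (adjusted p = 0.00203). Milk genes had −0.96 (adjusted p = 0.197), −1.61 with the slide set (adjusted p = 0.000123) and −2.55 on slides 1 to 4 (adjusted p = 2.45e-06), and Wnt targets 0.60 with the slide set (adjusted p = 0.039). With the slide as a block the adjusted p was 0.201, 0.395 and 0.00924 for these 3 lists, and with an estimated correlation and the slide set 0.782 for each. The block alone called macrophage (−0.66, adjusted p = 0.00735), luminal (−0.58, adjusted p = 0.0151), inflammatory and angiogenic (−0.56, adjusted p = 0.0331) and immediate early and stress genes (−0.31, adjusted p = 0.044). With an estimated correlation their adjusted p in the block fit was 0.905, 0.782, 0.905 and 0.782, that of Wnt targets was 0.782, and on slides 1 to 4 that of squamous and milk genes was 0.898 and 0.867.

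The gene called between LPA3 and LPA1 in limma was 4933406I18Rik, higher in LPA3 by 2.53 (SE 0.371, adjusted p = 0.0299; 1755 genes at an unadjusted p under 0.05). It had 2.99 with the slide set (adjusted p = 0.0427), 2.76 with the slide as a block, 3.27 on slides 1 to 4 and 2.85 on slides 5 and 6, and the limma count was 0 with the slide as a block (825 at an unadjusted p under 0.05). Genes of smallest p that did not pass were, upward, Ttc9 (2.53, SE 0.423), Rnf217 (1.54, SE 0.337), the MAP kinase phosphatase Dusp4 (2.02, SE 0.444) and Bloc1s2 (1.30, SE 0.294). Downward they were the peptide hormone gene Cck (−2.56, SE 0.432), Slc16a9 (−2.05, SE 0.348), Ggt5 (−1.39, SE 0.25), Hvcn1 (−1.74, SE 0.326) and endothelin Edn1 (−2.09, SE 0.412). Their adjusted p-values ran from 0.0508 for Ttc9, Cck and Slc16a9 to 0.264. On slides 5 and 6 alone 154 genes were called. Without LPA3 4 the count was 11.

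Cell division genes rose in LPA3 against LPA2 tumours, by a median of 0.81 (24 of 24 higher, camera adjusted p = 5.7e-11; adjusted p = 0.746 with an estimated correlation). Aurkb had 1.60 (SE 0.555), Bub1 1.42 (SE 0.628), Plk1 1.26 (SE 0.451) and Cdk1 1.16 (SE 0.385), all genes of mitosis, and 0 passed over the list alone (24 genes). The median was 0.72 with the slide set and 0.64 with the slide as a block. It was 1.08 on slides 1 to 4 and 0.60 on slides 5 and 6 (1 LPA3 tumour). Without LPA2 3, whose cell division score was the lowest of the 20 (−1.577), it was 0.51 (adjusted p = 3.93e-06). Basal keratinocyte and myoepithelial genes fell by 0.639 (13 of 15 lower, adjusted p = 0.00115; adjusted p = 0.746 with an estimated correlation), with Cnn1 at −3.05 (SE 0.743) and the myosin kinase Mylk at −1.36 (SE 0.414) among 3 that passed over the list alone. Endothelial genes fell by 0.655 (14 of 15 lower, adjusted p = 5.74e-05; adjusted p = 0.746 with an estimated correlation), with Vwf at −1.15 (SE 0.364) and Cldn5 at −1.21 (SE 0.603). Epithelial junction genes fell by 0.581 (13 of 16 lower, adjusted p = 0.0346; adjusted p = 0.831 with an estimated correlation), with the polarity gene Crb3 at −1.55 (SE 0.749) and E-cadherin Cdh1 at −1.16 (SE 0.523). On slides 1 to 4 these 3 lists had −0.48, −0.53 and −0.32, on slides 5 and 6 −0.22, −0.23 and −1.31, and with the slide as a block −0.50, −0.55 and −0.52. The calls ended for junction genes on slides 1 to 4 (adjusted p = 0.298) and for basal genes on slides 5 and 6 (adjusted p = 0.19). The junction call also ended without LPA2 3 (−0.36, adjusted p = 0.104), LPA2 4 (−0.60, adjusted p = 0.0544), LPA3 4 (−0.26, adjusted p = 0.487) or LPA3 5 (−0.40, adjusted p = 0.225).

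Adipocyte genes fell by 1.93 (13 of 14 lower, adjusted p = 4.47e-05; adjusted p = 0.746 with an estimated correlation), with Plin4 at −2.92 (SE 1.06), and had −0.84 with the slide set, −0.60 with the slide as a block (adjusted p = 0.0734), −0.96 on slides 1 to 4 (adjusted p = 0.0697) and −0.98 on slides 5 and 6. Macrophage genes rose by 0.62 (12 of 13 higher, adjusted p = 0.00115; 0.461 with the slide as a block, 0.119 on slides 1 to 4 and 0.169 on slides 5 and 6; adjusted p = 0.746 with an estimated correlation), with the complement gene C1qa at 0.94 (SE 0.418) and the scavenger receptor Cd163 at −1.11 (SE 0.564). With the slide set the calls ended for interferon response genes (0.54, adjusted p = 0.00148; 0.14 and 0.481; adjusted p = 0.746 with an estimated correlation), with Cxcl10 at 2.38 (SE 1.01) and Ifit1 at 1.31 (SE 0.681). They also ended for liver (−1.38, adjusted p = 0.000396; −0.22 and 0.335), skeletal muscle (−1.26, adjusted p = 0.00467; 0.02 and 0.908) and squamous differentiation genes (−0.65, adjusted p = 0.0258; −0.15 and 0.829), the last with loricrin Lor at −1.85 (SE 1.14). For these 3 lists an estimated correlation gave adjusted p-values of 0.746, 0.831 and 0.831, and liver genes were called on slides 1 to 4 as well (−0.60, adjusted p = 0.00517; adjusted p = 0.898 with an estimated correlation). Without LPA3 1 the interferon call ended (0.21, adjusted p = 0.107), and without LPA3 4 the median was 0.84. The muscle call ended without LPA2 2 (−0.88, adjusted p = 0.0629). That of squamous genes ended without LPA2 2 (−0.65, adjusted p = 0.0603), LPA2 5 (−0.27, adjusted p = 0.227), LPA3 3 (−0.61, adjusted p = 0.0693) or LPA3 5 (−0.59, adjusted p = 0.0841), and the median was −0.999 without LPA2 4.

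LPA3 and LPA2 tumours differed in 0 single genes in limma, with 1778 at an unadjusted p under 0.05. The smallest p-values upward were those of 4933406I18Rik (2.22, SE 0.371, adjusted p = 0.17), Cnih4 (0.92, SE 0.203), Ddias (1.88, SE 0.439), the inflammasome sensor Nlrp1a (1.11, SE 0.262) and Srrt (1.31, SE 0.311). Downward they were the resistin family gene Retnla (−3.22, SE 0.689), Edn1 (−1.88, SE 0.412), Cck (−1.95, SE 0.432), Slx1b (−1.34, SE 0.297) and Zbtb20 (−1.59, SE 0.353). All but the first of these 10 had an adjusted p of 0.467. On slides 5 and 6, with 1 LPA3 tumour, 163 genes were called. The 15 other lists had adjusted p-values from 0.0517 (hormone sensing, 10 of 10 lower, median −0.53, and brain) to 0.993. B and plasma cell genes (−0.87, adjusted p = 0.00175) and Wnt targets (0.60, adjusted p = 0.0234) were called too with the slide set (adjusted p = 0.782 for both with an estimated correlation). Both were also called with the slide as a block (−0.57 and 0.39, adjusted p = 0.0084 and 0.00623; adjusted p = 0.75 and 0.782 with an estimated correlation). On slides 1 to 4 they and milk genes were called, B and plasma cell genes downward and the other 2 upward (adjusted p = 0.0265, 0.00827 and 0.0485; adjusted p = 0.898, 0.843 and 0.898 with an estimated correlation). For mesenchymal transition, luminal and neutrophil genes the median, the mean and camera's direction differed in sign.

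Over the 100 tests of 25 lists in 4 comparisons, camera with a preset correlation of 0.01 called 36, 14 upward and 22 downward. With an estimated correlation 0 were called in the fit without the slide, with a lowest adjusted p of 0.199. It called 1 of 100 with the slide set, with the slide as a block and on slides 1 to 4, each time basal keratinocyte and myoepithelial genes in ATX (adjusted p = 0.00845, 0.02 and 0.0289). The second lowest values there were 0.0828, 0.101 and 0.516. The rotation test fry, which asks only whether the genes of a list move one way, called 1, hormone sensing in ATX (adjusted p = 0.0118). Of the 36, 22 were also called in the same direction with the slide set, and 17 with the slide as a block too.

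Tumours of 1 genotype resembled each other slightly more than those of other genotypes. The correlation over centred genes averaged 0.0253 in 40 pairs within a genotype and −0.0718 in 150 pairs between genotypes. The difference was 0.0971 (one-sided permutation p = 0.0147). By genotype the pairs averaged 0.0959 for ATX, −0.0351 for LPA1, 0.021 for LPA2 and 0.0195 for LPA3. The same difference between slide sets in place of genotypes was 0.262 (permutation p = 3e-05). The genotype difference was 0.0469 with the slide set removed and 0.101 on slides 1 to 4 (permutation p = 0.0305 and 0.0184). It was 0.0637 without ATX 2 and 0.0648 without ATX 4 (permutation p = 0.0599 and 0.0578). The permutations ignored single slides (slide 2 held 3 LPA3 tumours), which stay open.

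The 2 arrays of the tumour of LPA1 mouse 4, on slides 7 and 4, differed by an SD of 0.885 over genes and correlated at r = 0.766, while the 44 pairs of arrays from different mice of 1 genotype had a median SD of 1.06 and a median r of 0.524. These correlations are across genes, which are not independent replicates. ATX 2 and ATX 4 were closer to each other than those 2 arrays (SD 0.668, r = 0.858), and so were LPA3 1 and LPA3 3 (SD 0.785, r = 0.774). Of 209 pairs of arrays of different tumours 27 had a smaller SD than the repeat arrays, 21 of them on slides 5 and 6, and 2, these close pairs, had a higher r. Over 817 genes with 2 agreeing probes 9 had a smaller SD, 7 of them on slides 5 and 6. Counting each of the 2 close pairs as 1 sample left 0 genes in ATX against the receptors (1465 at an unadjusted p under 0.05 in limma), 1 in the F test and a similarity difference of 0.0477 (permutation p = 0.128), an alternative chosen after seeing the data.

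Across the 20 tumours, 6 relations between list scores were tested. Scores of mesenchymal transition and epithelial junction genes were opposed (Pearson r = −0.747, permutation p = 0.00013, adjusted p = 0.00078; Spearman rho = −0.627, permutation p = 0.00361). LPA1 4 had the highest mesenchymal score and the lowest junction score of the 20 tumours, 1.31 and −1.26. LPA1 3 had the lowest mesenchymal score, −1.17, with a junction score of 0.54. The mesenchymal score followed that of fibroblast and collagen genes (r = 0.897), with which the list shares 0 genes, and also the endothelial and macrophage scores (r = 0.69 and 0.671). With the fibroblast score removed from both, the mesenchymal and junction scores had r = −0.548, and with the macrophage score removed r = −0.56. LPA1 4 also had a fibroblast score of 1.537, a macrophage score of 1.544 and a class II score of 1.755, so the relation does not part a change in tumour cells from the share of stroma and immune cells. These values were looked at after the relation was seen. Without these 2 tumours r was −0.643 (permutation p = 0.00451), on slides 1 to 4 −0.786 (n = 13, permutation p = 0.00093) and on slides 5 and 6 −0.504 (n = 7, exact p = 0.242).

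**Figure D3:**
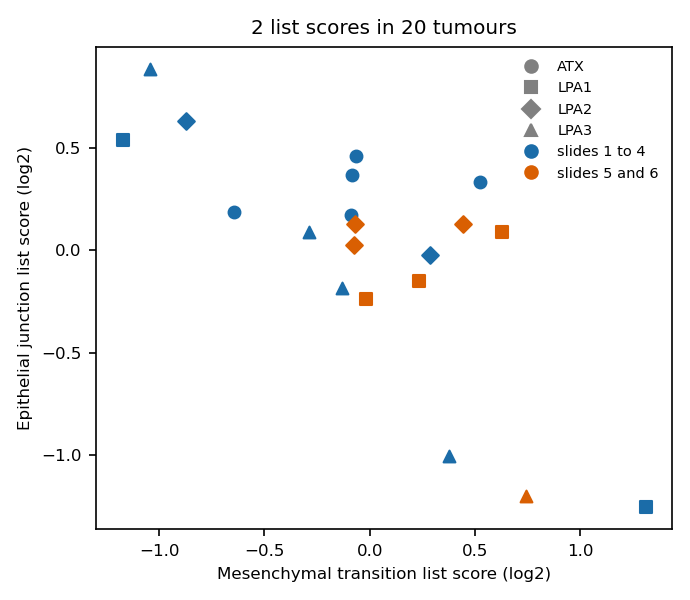
Mesenchymal transition score (horizontal) against epithelial junction score (vertical), both in log2 units relative to the mean of 20 tumours. Each point is 1 tumour, shaped by transgene and coloured by slide set. The scores were opposed (r = −0.747), with LPA1 4 at 1.31 and −1.26.

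Scores of T and NK cell and of B and plasma cell genes rose together (r = 0.522, permutation p = 0.0211, adjusted p = 0.0356; rho = 0.51, permutation p = 0.0236), with r = 0.641 without the 2 tumours farthest from the median. The relation passed in only 11 of 20 fits that left 1 tumour out (r = 0.463 to 0.596). Within slides 1 to 4 r was 0.546 (permutation p = 0.0533) and on slides 5 and 6 it was 0.674 (n = 7, exact p = 0.0903). Adipocyte and endothelial scores correlated at r = 0.499 (permutation p = 0.0238, adjusted p = 0.0356; rho = 0.534, permutation p = 0.0169) and at 0.515 without the 2 farthest tumours. They too passed in only 11 of 20 fits that left 1 tumour out (r = 0.452 to 0.569). Within slide sets that relation did not pass (r = 0.351, permutation p = 0.241 on slides 1 to 4; 0.454, n = 7, exact p = 0.304 on slides 5 and 6). Squamous and basal scores correlated at r = 0.512 (permutation p = 0.0211, adjusted p = 0.0356; rho = 0.373, permutation p = 0.107). That relation rests on ATX 5 and LPA2 5, without which r was 0.339 (permutation p = 0.167). Within slide sets it was 0.358 (permutation p = 0.236) and 0.811 (n = 7, exact p = 0.0601). Cell division was not related to fibroblast and collagen genes (r = −0.0851, permutation p = 0.724; rho = 0.00301, permutation p = 0.992), with r = −0.408, −0.00204 and 0.459 without the 2 farthest tumours and within the slide sets. Nor was it related to milk genes over all tumours (r = 0.284, permutation p = 0.23; rho = 0.14, permutation p = 0.554; 0.364 without the 2 farthest). Within slides 1 to 4 the latter r was 0.254 (permutation p = 0.406) and on slides 5 and 6 it was −0.855 (n = 7, exact p = 0.00575, adjusted p = 0.0345).

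The 12 genes of largest spread over the tumours were led by Csn2 (SD 3.27, from 0.84 in LPA2 3 to 9.80 in ATX 1), the homeobox gene Cdx1 (SD 3.21, from −9.97 in ATX 3 to 6.14 in ATX 1), the neuregulin Nrg2 (SD 3.12, from −6.30 in LPA1 3 to 5.76 in LPA1 2), Myot (SD 3.05) and Rspo1 (SD 2.97, from −7.21 in LPA3 3 to 4.96 in ATX 1). Kir3dl1 (2.95), Pck1 (2.89), Atp1b4 (2.87), Csn1s2a (2.84), Fabp1 (2.80), Afp (2.76) and Kcne2 (2.70) followed. For Atp1b4, Fabp1 and Afp the SD was under 1 within each slide set, with means on slides 1 to 4 of −6.88, −6.42 and −6.65 and on slides 5 and 6 of −1.16, −0.921 and −1.13.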

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

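The counts of splits, the test of a larger luminal share and that of near-identical tumours counted more than once were set before their results were seen, and all other tests of explanations in this part were chosen after. Of the 192 groups of 5 tumours examined (100 list scores and 92 gene values), 26, or 13.5%, held a tumour set apart from the other 4 by a gap above 0.71 of the whole range. Chance alone sets apart about 1 in 20 such groups. Scores are relative to the mean of the 20 tumours, and the range of the other 4 tumours is in brackets.

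ATX 5 stood apart in 7 values. Its scores were 2.44 for inflammatory and angiogenic mediators (−0.826 to −0.17), 2.37 for neutrophil genes (−1.47 to −0.921), 1.73 for squamous differentiation (−1.24 to −0.556) and 0.79 for fibroblast and collagen genes (−0.65 to −0.326). Its log2 ratios were −0.786 for Lpar1 (−2.01 to −1.9), −0.147 for Pnmt (2.52 to 3.57) and 1.74 for Nabp1 (2.04 to 2.13). ATX 4 had −0.206 for 4933406I18Rik (−0.058 to 0).

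LPA1 4 had scores of 1.76 for class II antigen presentation (−0.919 to −0.502), 0.987 for inflammatory and angiogenic mediators (−0.464 to −0.175) and −0.596 for hypoxia and glycolysis genes (−0.028 to 0.177), and a Nabp1 ratio of 1.5 (0.803 to 0.991). LPA1 3 had −1.32 for endothelium (0.242 to 0.774) and an Lpar1 ratio of −2.89 (−0.196 to 0.302). LPA2 3 had 1.28 for B and plasma cell genes (−0.383 to −0.26), 0.636 for epithelial junction genes (−0.024 to 0.13) and a Wfdc12 ratio of 4.14 (0.22 to 1.28). LPA2 5 had 0.921 for Wnt targets (−0.565 to −0.151) and LPA2 4 a Sostdc1 ratio of −4.89 (−2.25 to −1.5).

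LPA3 2 had 0.45 for B and plasma cell genes (−0.946 to −0.762), −0.625 for the LPA axis (−0.093 to 0.083) and −0.463 for inflammatory and angiogenic mediators (0.236 to 0.469). LPA3 5 had a Sostdc1 ratio of −6.73 (−3.69 to −3.05). LPA3 4 had 1.94 for liver (−1.12 to −0.779), 1.55 for skeletal muscle (−1.26 to −0.929) and 0.037 for endothelium (−0.62 to −0.549), and it is the LPA3 tumour on slides 5 and 6.

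On slides 5 and 6 the log2 ratios were narrow, for which no biological explanation was tested other than the share of tissue around the tumours. Fat and muscle there were excluded as the whole cause, since the lowest liver median on these slides exceeded the highest elsewhere by 1.53. A single factor that shrinks every ratio was excluded as the whole cause: the liver, adipocyte and skeletal muscle medians lay 0.533 (SD 0.17), 1.26 (SD 0.692) and 1 (SD 0.47) above the values such a factor gives, each in 7 of 7 arrays. It stays open for the other genes: the slope against the other arrays was 0.502 ± 0.112 for 338 genes above and 0.402 ± 0.0242 for 1353 genes below the reference (SD, n = 7 arrays), larger above in 6 of 7 arrays but not in LPA3 4 (mean difference 0.0993, SD 0.116). Another reference pool stays open: it would not make the tumours vary less among themselves (ratio of SDs 0.581), but they may differ less by themselves, since a pair elsewhere differed by as little as 0.829 against up to 0.852 within these slides, leaving out the 2 close pairs below (0.668 and 0.785), each perhaps 1 tumour.

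Hormone sensing genes were higher in ATX tumours, with a score difference of 1.37 (exact permutation p = 0.000774 over 15504 splits, n = 5 and 15). A slide batch as the whole cause was excluded, since the smallest median difference in the 3 slide settings was 1.24 and the score difference on slides 1 to 4 was 1.6 (exact p = 0.00155). A larger luminal share, as the luminal list measures it, did not account for all of the difference. The score minus that of luminal genes still differed by 1.02 (exact p = 0.0112). That p ignores the slides and counts the close pairs as separate tumours. A larger share of hormone sensing cells stays open, since the luminal list does not measure it. With each close pair counted once the score difference was 1.16 (exact p = 0.00392). The list's camera adjusted p was then 9.5e-07 (preset correlation). ATX 3, which also scored high, stayed a separate sample. Over all genes it differed from ATX 4 by an SD of 0.829 and from ATX 2 by 0.877, against 0.885 for the repeat arrays. Over genes with 2 agreeing probes these values were 0.619 and 0.693, against 0.575. That the ATX transgene raises hormone sensing genes stays a hypothesis, found and tested on the same tumours and not called with an estimated correlation (adjusted p = 0.199).

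ATX 2 and ATX 4, and LPA3 1 and LPA3 3, were as alike as 2 arrays of 1 tumour, for which no biological explanation was tested. A shared slide was excluded for the ATX pair, which lay on 2 slides. For the LPA3 pair it stays open: over genes with 2 agreeing probes the other pairs on its slide differed by an SD of at least 0.747, against 0.469, but over all genes by as little as 0.864, against 0.785 for this pair and 0.885 for the repeat arrays. Had 1 tumour been hybridised more than once, probes of 1 gene would follow each other no more in the difference than in that of the repeat arrays (r = 0.614). The value was 0.508 for the LPA3 pair, which allows it, and 0.719 for the ATX pair, whose interval of 0.614 to 0.802 overlaps that of the repeat arrays and leaves it open.

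The calls were counted again in 100 splits of the same tumours, the real one included. These splits ignored the slides and took close pairs of tumours as independent. Within that limit 1 of 100 splits was as large for the F test (6 genes, highest other 2). For ATX against the receptors it was 2 of 100 (19 genes, highest other 979). For ATX against LPA2 it was 4 of 100 (1 gene, highest other 9), and against LPA3 2 of 100 (19 genes, highest other 24). By these shares chance was unlikely, but it cannot be excluded. Several counts were examined without adjustment, and the real groups hold the close pairs of tumours and share slides. The split with 979 genes set LPA1 1, 2 and 5 and LPA2 1 and 5, all on slides 5 and 6, against the rest, which points to the slides as the larger structure, and with the slide as a block the 4 real counts were 0 in limma (1050, 1489, 1365 and 1385 at an unadjusted p under 0.05). With near-identical tumours counted once they were 1, 0, 0 and 2 (1072, 1465, 1619 and 1202 at an unadjusted p under 0.05). Nor can chance be excluded for LPA3 against LPA1 (1 gene, 11 of 100, highest other 478). That highest split put the 4 tumours on slides 5 and 6 together. For LPA2 against LPA1, LPA3 against LPA2 and ATX against LPA1 the real count was 0 in limma (697, 1778 and 1715 at an unadjusted p under 0.05; highest other 1, 69 and 120). There all 100 of 100 splits are as large by construction, which says nothing about chance.

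Nor can it be excluded for the number of lists called in any of the 4 comparisons: 11 in ATX against the receptors (30 of 100 splits as many, highest other 16), 6 in LPA2 against LPA1 (88 of 100, highest other 14), 9 in LPA3 against LPA1 (66 of 100, highest other 16) and 10 in LPA3 against LPA2 (36 of 100, highest other 16).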

How the results depend on the processing

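The slides limit the results, since ATX had no tumour on slides 5 and 6, and signal over background was not analysed here, so dim probes were not weighed. In each case below the cause was not tested. Scaling to the same spread, the run of slides as a block, slides 1 to 4 alone, slides 5 and 6 alone and near-identical tumours counted once were chosen after seeing the data. For single genes, lists and numbers of lists called, 3185 values counted as the same in the alternatives fixed beforehand. Of the rest 387 were weaker, 45 stronger, 12 moved and 6 reversed, and in the added alternatives these numbers were 359, 94, 4, 1 and 7. A gene called in neither fit counted as the same even where its sign turned. Lpar1 in ATX against the receptors, at −0.793 and at 0.338 with the slide as a block, is such a gene. Numbers of lists counted as the same when they changed little.

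The F test called 18 genes with every probe alone, 3343 with array weights, 14 with the slide set, 3 with the repeat array alone, 12 at an adjusted p under 0.1, 69 on slides 5 and 6 and 1 with near-identical tumours counted once. It called 0 in limma with the slide as a random or a fixed block, the same spread, the run of slides and slides 1 to 4 (1050 with the fixed block and 1785 on slides 1 to 4 at an unadjusted p under 0.05). Without 1 tumour it called 0 to 37, with 0 without ATX 2 or ATX 4 and 37 without ATX 1.

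ATX against the receptors gave 33 genes with quantile normalization, 45 with every probe, 9 with the probe of largest SD, 10 with the robust model, 2522 with array weights (876 higher, 1646 lower), 5 with the slide as a random block, 29 with the first array, 10 with the repeat array and 54 at an adjusted p under 0.1. It gave 0 in limma with the slide as a fixed block (1489 at an unadjusted p under 0.05), on slides 1 to 4 (1247), with the same spread and with near-identical tumours counted once (1465). Without 1 tumour it gave 0 to 116: 0 without ATX 2, 1 without ATX 4, 116 without ATX 1, 68 without ATX 5 and 42 without LPA1 3. Against LPA2 alone it gave 0 with quantile normalization, the slide set, the same spread, the run of slides and near-identical tumours counted once, and against LPA3 80 with the slide set, 5 on slides 1 to 4 and 2 with near-identical tumours counted once.

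LPA2 against LPA1 gave 6 genes on slides 1 to 4 and 0 to 0 without 1 tumour. LPA3 against LPA1 gave 3 with quantile normalization, 6 with every probe, 4 each with the probe of largest SD, the robust model and the repeat array, 828 with array weights, 5 at an adjusted p under 0.1 and 154 on slides 5 and 6. It gave 0 in limma with the slide as a random or fixed block (825 at an unadjusted p under 0.05 with the latter), the first array, only the groups compared, the run of slides and slides 1 to 4 (1676), and 0 to 11 without 1 tumour, 11 without LPA3 4. LPA3 against LPA2 gave 1079 with array weights, 163 on slides 5 and 6, 1 with near-identical tumours counted once, and 0 to 1 without 1 tumour (1 without LPA3 3).

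The mice share only a number across genotypes. With the mouse number as a block the F test called 2 genes, ATX against the receptors 16 and LPA3 against LPA1 0, and 38 lists were called. Deviations from the group means of the 30 pairs with the same number correlated at −0.355 to 0.319, 9 of them over 0.1, and 4 of 20 tumours correlated best with their own number, so the numbers give no hint of a pairing.

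Of the lists, 0 were called with an estimated correlation in the fit without the slide, 1 with fry and 35 to 50 without 1 tumour. An estimated correlation called 1 list, basal keratinocyte and myoepithelial genes in ATX against the receptors, with the slide set (adjusted p = 0.00845), with the slide as a block (adjusted p = 0.02), with the run of slides (adjusted p = 0.0245) and on slides 1 to 4 (adjusted p = 0.0289). In ATX against the receptors the median of luminal genes turned to −0.0606 with the slide set and −0.102 with the run of slides, and that of skeletal muscle genes to 0.462 with the slide as a block (called there, adjusted p = 0.0398; adjusted p = 0.905 with an estimated correlation), 0.241 with the slide set, 0.342 with the run of slides (called, adjusted p = 0.0411; adjusted p = 0.946 with an estimated correlation) and 0.288 on slides 1 to 4. In LPA3 against LPA1 liver genes turned to 0.102, 0.202, 0.146 and 0.478 in the same settings, and were called upward with the slide set (adjusted p = 0.0246) and on slides 1 to 4 (adjusted p = 0.00872). On slides 1 to 4 cell division genes turned to −0.427 (called, adjusted p = 0.00443) and skeletal muscle genes to 0.563. With an estimated correlation the turned calls of this comparison had adjusted p-values of 0.872 and 0.898 for liver and 0.898 for cell division genes. In LPA3 against LPA2 skeletal muscle genes turned to 0.0209 with the slide set.

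Against the reference, a mean of at least 2 in size left 54 genes higher and 499 lower, slides 1 to 4 gave 466 and 1595, and leaving out 1 tumour 261 to 311 and 1008 to 1089. The similarity difference was 0.0477 with near-identical tumours counted once and 0.0637 (without ATX 2, permutation p = 0.0599) to 0.128 without 1 tumour. The relations on slides 1 to 4 given here use the repeat array of LPA1 4 in place of the mean of its 2 arrays, and so differ from those of the report. Squamous and basal scores correlated at 0.394 with quantile normalization, 0.377 on slides 1 to 4 and 0.409 to 0.644 without 1 tumour (p under 0.05 in 12 of 20). T and B cell scores had 0.525 with quantile normalization (adjusted p = 0.0581), 0.604 on slides 1 to 4, 0.49 with near-identical tumours counted once and 0.463 to 0.596 without 1 tumour (11 of 20). Adipocyte and endothelial scores had 0.354, 0.34 and 0.485 in the same settings, 0.382 with the same spread and 0.452 to 0.569 (11 of 20). Mesenchymal and junction scores had −0.799 to −0.658 (20 of 20), cell division and fibroblast scores −0.28 to 0.101 (0 of 20), and cell division and milk scores 0.0979 to 0.495 (1 of 20).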

Other observations

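Csn1s2a and Csn2 varied little on slides 5 and 6, where the 7 tumours came from 3 genotypes. Csn1s2a had 2.16 ± 0.0943 (SD, n = 7) there with an SD of 2.68 (n = 13) on slides 1 to 4, and Csn2 had 2.09 ± 0.284 and 7.09 ± 2.71. Within slides 1 to 4 the casein Csn2 ran from 0.84 in LPA2 3 to 9.80 in ATX 1. The milk list as a whole was less even, with tumour medians of 1.35 ± 0.411 (n = 7) on slides 5 and 6, where ratios spread less altogether (SD within an array 0.825 to 0.903).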
